A study of Mus musculus with 16 samples.

How the data were processed

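BM67 is a cell line from a prostate tumour of a mouse in which Pten is deleted by a prostate-specific Cre. Per the labels, the cells grew in medium with 5% serum and carried a pGIPZ vector with 1 hairpin against the estrogen receptor alpha or a non-silencing one. Cytosolic lysates were run on a sucrose gradient from 5% to 50% to isolate RNA bound by more than 3 ribosomes, and total cytosolic RNA was isolated in parallel. Libraries were made by Smart-seq2, which copies poly(A) RNA and amplifies the cDNA by PCR without molecular identifiers, from 10 ng RNA, with 80 pg cDNA taken into tagmentation. The protocol gives no strand information.

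The deposited file holds raw read counts per gene symbol, in 1 column for each of the 16 libraries, as whole numbers with no normalization. The authors aligned reads with HISAT2 to GRCm38. The HISAT2 version, the counting tool, the gene annotation and the treatment of reads with several alignments are not given in the sources used here. Columns were paired with samples by the identifiers in the labels, and 0 columns were left unmapped. Gene positions come from the RefSeq annotation of GRCm38, which matched 10343 of the 10880 tested genes (95.1%).

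Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes passed filterByExpr over the 4 groups, libraries were scaled by TMM, and dispersions were fitted with robust settings to all 16 libraries with 1 mean per group. The quasi-likelihood test gave 2-sided p-values, adjusted by Benjamini-Hochberg over all genes tested in each contrast, with a threshold of 0.05. The SE of a log2 fold change is its size divided by the square root of the F statistic. Contrasts were shERa against shCtrl in cytosolic RNA, the same in polysome-associated RNA, the difference between these changes, and polysome-associated against cytosolic RNA in shCtrl, with the last also run in shERa. For Esr2, a count of 0 was bounded by 3 reads of the total.

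Modes were set from these tests. Abundance genes passed in cytosolic and polysome-associated RNA in 1 direction with no call for the difference. Offset genes passed in cytosolic RNA, with a call for the difference in the opposite direction and a smaller change on polysomes. Translation genes passed on polysomes, with a call for the difference in the same direction and no cytosolic call. The slope of polysome on cytosolic change runs through the origin, over genes past the cytosolic threshold, which pulls it down; its error is a jackknife over 8 replicates.

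Of 34 gene lists of pathways and cell type markers, 29 had at least 3 tested members and were tested with camera from limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted by Benjamini-Hochberg over lists. Camera was repeated with an estimated correlation, and fry was run on the lists. Named genes were, per contrast, the 10 highest and 10 lowest log2 changes among called genes with a mean of at least 5 CPM and an established symbol, and for the shERa contrasts no overlap between groups. The rule also named up to 10 genes per mode by size of change, up to 4 called genes per list, Esr1, Esr2, Ar, Pten and the enzymes of wobble uridine modification; the text prints part of these and names others after their values were seen, as stated beside them. The contrasts, tests, threshold, modes, lists, naming rule and the alternatives below were chosen before the data were examined.

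The pipeline was tested on simulated data with 200 changed genes. Of 50 genes simulated at 4-fold in cytosolic RNA alone, edgeR called 49 in the cytosolic contrast and 42 in the difference between contrasts, and of 50 at 2-fold 26 and 0. Of 10538 unchanged genes it called 8, 7 and 5 in the cytosolic, polysome and difference contrasts. No 2 libraries were copies of each other: over 24 replicate pairs, chi-square per degree of freedom ran from 6.53 to 62.6. Alternatives were DESeq2's size factors in edgeR, library size alone, other low-count filters (none, or a mean of 50 reads), DESeq2 1.42.0, limma voom, replicate and culture blocks, analysis of partial variance, the replicates that the labels list as also measured on microarrays, fits on the 8 libraries of a contrast, a threshold of 0.15, and leaving out each replicate in turn. Depth ran from 2769566 to 10091075 reads. A comparison of codon and UTR features was not run, as no transcript sequences were among the sources used here.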

Results

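RNA was sequenced from BM67 cells, a mouse prostate cancer cell line deficient in the tumour suppressor Pten, that carried a stable short hairpin RNA against the estrogen receptor alpha (shERa) or a non-silencing hairpin (shCtrl). Total cytosolic RNA and RNA bound by more than 3 ribosomes (polysome-associated RNA) were each sequenced from 4 replicates per hairpin, which made 16 libraries in 4 groups. Reads assigned to genes numbered 8342077, 5942931, 5593008 and 5348207 in cytosolic shCtrl replicates 1 to 4 and 8901672, 9620685, 9953297 and 10091075 in cytosolic shERa. Polysome-associated libraries held 5774729, 4025749, 2769566 and 2816961 reads in shCtrl and 4170973, 3474482, 2891115 and 2900030 in shERa. The files held 21903 gene symbols, 14906 of them with at least 1 read, and 10880 genes were tested. Levels are CPM, read counts per 1e6 reads of a library scaled by TMM, given as mean ± SD with n = 4, and changes are log2 fold changes ± SE. The labels do not say whether replicates are separate cultures, so p-values measure the spread between these samples. Reads carried no molecular identifiers, so floors on counts of 0 cover counting error only.

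In a principal component analysis, component 1 (35.0% of the variance) placed cytosolic control library 1 at -36.5, against 13.9 to 16.9 for the 3 other cytosolic control libraries and -75.3 to -61.0 for the 4 cytosolic shERa libraries. That library held 2.86% of its reads on mitochondrially encoded genes, against 1.59%, 1.80% and 1.52% in the other cytosolic controls and 3.26 ± 0.40% in cytosolic shERa RNA.

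**Figure D1:**
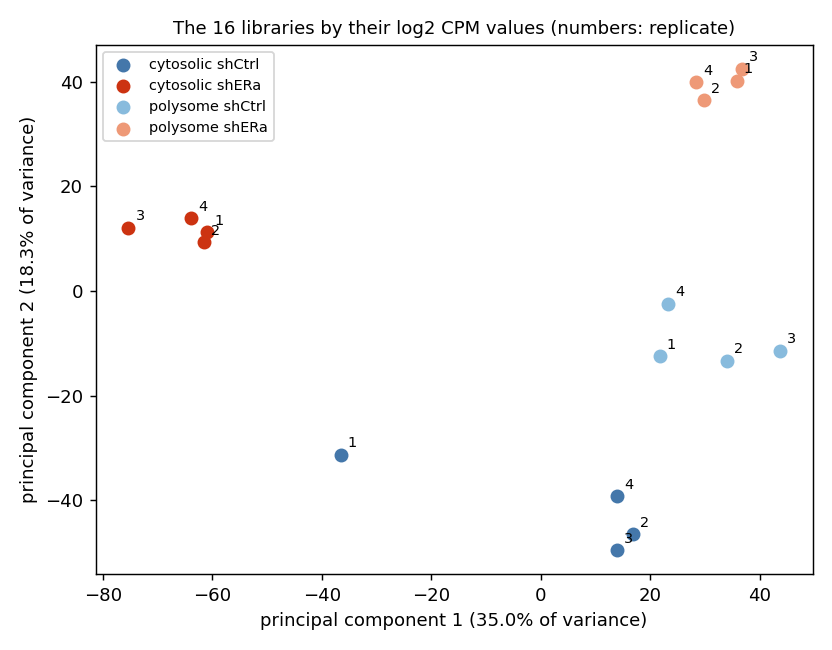
Scores of the 16 libraries on principal components 1 (35.0% of the variance) and 2 (18.3%) of log2 CPM; each point is 1 library, with its group and replicate marked. Cytosolic control library 1 lies at -36.5 on component 1, and the other 3 cytosolic controls lie from 13.9 to 16.9.

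Esr1 (chromosome 10, 4611989 to 5005633 in GRCm38), which encodes the hairpin's target, fell in both kinds of RNA. Cytosolic Esr1 went from 24.1 ± 5.69 to 7.50 ± 1.40 CPM, with 27.9, 16.1, 28.4 and 23.97 CPM in the 4 controls and 8.81, 6.004, 6.62 and 8.56 CPM in the 4 shERa libraries. On polysomes it went from 24.8 ± 2.90 to 5.48 ± 2.10 CPM. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the log2 changes were -1.68 ± 0.28 (adjusted p = 0.000148) and -2.20 ± 0.31 (adjusted p = 6.15e-05), each lower in 4 of 4 shERa libraries. The polysome change did not pass the test of a difference from the cytosolic change (-0.52 ± 0.42, adjusted p = 0.406, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Esr2, which encodes the other nuclear estrogen receptor, had 0 of 92616557 reads, which allows up to 0.0324 CPM over the 16 libraries. Ar, the androgen receptor gene (chromosome X, 98148757 to 98323218), had a log2 change of 0.12 ± 0.29 in cytosolic RNA, which did not pass, and fell on polysomes by 1.22 on the log2 scale, from 31.03 ± 10.6 to 13.3 ± 2.76 CPM. For Ar, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave adjusted p = 0.783 in cytosolic RNA, 0.0220 on polysomes and 0.0363 for the difference between them (-1.34 ± 0.43). On polysomes, Ar lost its call without any 1 of shCtrl replicate 3 and shERa replicates 2, 3 and 4 (adjusted p up to 0.0940, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The Ar difference between fractions lost its call without any 1 of shCtrl replicates 2, 3 and 4 and shERa replicates 1, 2, 3 and 4 (adjusted p up to 0.130, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Pten had 11.7 to 52.7 CPM in cytosolic shCtrl and 30.8 to 55.3 CPM in cytosolic shERa libraries. Counts per gene do not show whether a deleted part of the gene was read. Pten reads had log2 changes of 0.77 ± 0.36 in cytosolic RNA and -0.04 ± 0.39 on polysomes, and neither passed. The cytosolic change of Pten was 1.44 without shCtrl replicate 1 (adjusted p = 0.000285) and without cytosolic control library 1 alone (adjusted p = 0.000810), by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. By the same test it passed with a replicate block (0.93, adjusted p = 0.02235), and it passed by limma voom (0.92, adjusted p = 0.0242). The Pten difference between the polysome and cytosolic changes passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment without shCtrl replicate 1 (-1.11, adjusted p = 0.0415). It also passed without cytosolic control library 1 alone (-1.49, adjusted p = 0.0122).

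**Figure D2:**
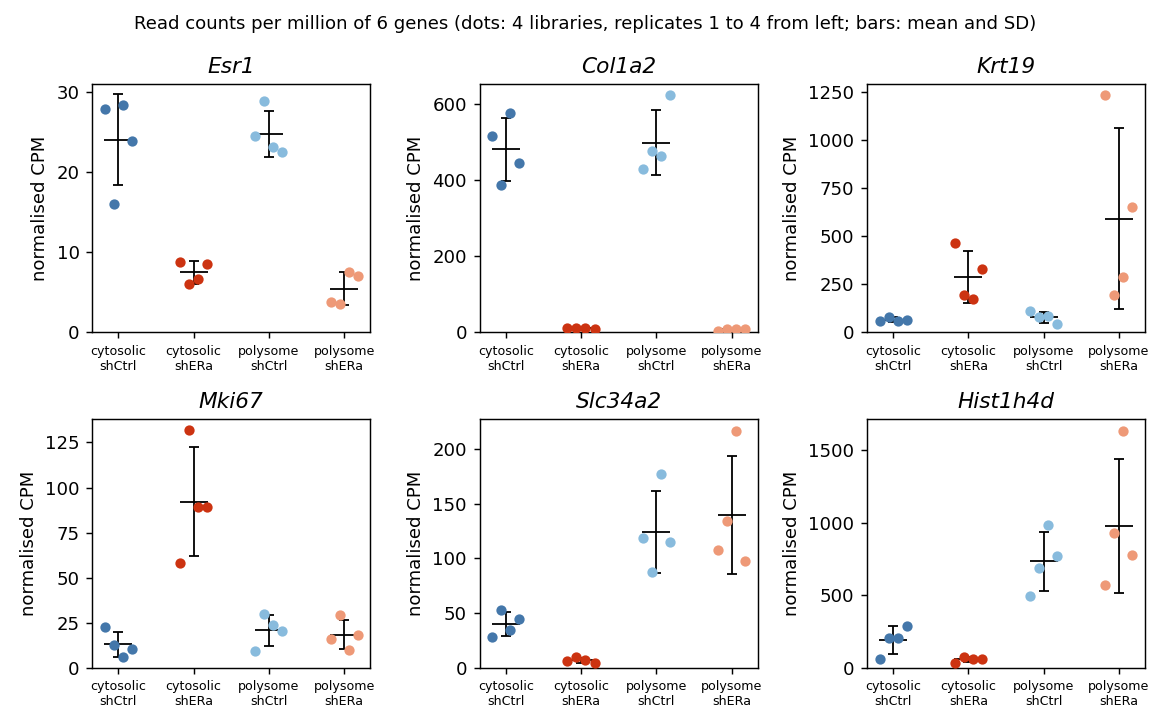
Normalised CPM of Esr1, Col1a2, Krt19, Mki67, Slc34a2 and Hist1h4d in the 4 groups, on linear axes from 0; points are single libraries and bars are means with SD, n = 4. Esr1 lies at 24.1 ± 5.69 CPM in cytosolic shCtrl RNA and at 7.50 ± 1.40 CPM in cytosolic shERa RNA.

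The comparison of cytosolic RNA asked which mRNA levels differ between shERa and shCtrl cells. Collagen mRNAs fell: Col1a2 (chromosome 6, 4505618 to 4541543), a chain of type I collagen, went from 481 ± 82.5 to 11.3 ± 1.37 CPM, and Col3a1, Col6a2 and Col6a3, chains of type III and type VI collagen, changed by -4.43 ± 0.43, -4.11 ± 0.39 and -4.26 ± 0.49. Postn, a secreted matrix protein gene, changed by -4.29 ± 0.43 and Pdgfrb, a receptor for platelet-derived growth factor, by -4.32 ± 0.33. The other genes among the 10 largest falls were Npffr1, a neuropeptide receptor gene (-6.43 ± 0.51), Cd200, an immunoregulatory membrane protein gene (-5.42 ± 0.53), Sprr1b, a cornified envelope precursor gene (-4.23 ± 0.28), and Uchl1, a deubiquitinase gene (-3.87 ± 0.47). Cdx2, an intestinal homeobox gene (chromosome 5, 147300900 to 147307249), rose from 1.47 ± 1.16 to 14.2 ± 4.13 CPM, and Wnt4, a secreted Wnt ligand gene, from 4.23 ± 1.43 to 37.9 ± 28.4 CPM. The others among the 10 largest rises were Zfp445, Gda, Tmcc3, Haus3, Ptprf, Kif20b, Cep290 and Nov, with log2 changes from 3.00 for Nov to 3.80 for Zfp445. Gda encodes guanine deaminase, Haus3 an augmin subunit of the spindle, Kif20b a kinesin of cell division, Cep290 a protein of the cilium base and Ptprf a receptor phosphatase. The naming rule kept only called genes with a mean of at least 5 CPM in which 4 of 4 shERa libraries lay beyond every shCtrl library. The 10 largest falls and rises are the largest within that set, so their lack of overlap is no separate result.

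In all, 3580 of the 10880 genes tested differed in cytosolic RNA, 2115 higher and 1465 lower, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (two-sided, adjusted p under 0.05). Among these the median size of the log2 change was 1.03. In 3353 genes (30.8%) the 4 shERa and 4 shCtrl libraries did not overlap, where chance gives 2.86%. The share of called genes that were higher, 59.1%, depended on scaling: DESeq2's size factors moved the median of all genes by -0.12 and gave 46.8%, and library size alone moved it by 0.13 and gave 73.9%. Leaving out replicates moved that share too. Without shERa replicate 1, 1812 genes were higher and 1866 lower (49.3% higher), and without shCtrl replicate 2, 1301 of 2443 were higher. The 3 replicates per hairpin also measured on arrays gave 2018 genes, 1284 higher and 734 lower.

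Of 29 TGF-beta and extracellular matrix genes, 15 fell and 2 rose in cytosolic RNA (17 and 3 adjusted over the list alone), with a median log2 change of -1.13. Col1a2 changed by -5.41 ± 0.26, and the 2 that rose were Skil (1.21 ± 0.25), a repressor of TGF-beta signalling, and Id1 (0.90 ± 0.16), an inhibitor of basic helix-loop-helix factors, both named after their values were seen. The list was lower than other genes (camera, adjusted p = 3.95e-06, and adjusted p = 0.560 with an estimated correlation). Its median in cytosolic control library 1 lay -0.01 from the other controls, against -1.14 for shERa.

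Of 79 cytosolic ribosomal protein mRNAs, 32 fell and 2 rose (34 and 3 adjusted over the list alone; median -0.41). Uba52, which encodes a ubiquitin fused to a ribosomal protein, changed by -1.22 ± 0.29, Rps14 by -0.99 ± 0.22, Rpl18a by -0.93 ± 0.17 and Rpl10a by -0.91 ± 0.18. Rpl5 (0.58 ± 0.20) and Rpl23 (0.80 ± 0.20), named after their values were seen, rose. Of 18 replication dependent histone genes, whose mRNAs are made in S phase and lack a poly(A) tail, 11 fell and 0 rose (13 and 0 adjusted over the list alone; median -1.16). Hist1h4d went from 191 ± 93.8 to 58.4 ± 16.4 CPM, Hist1h1e changed by -1.64 ± 0.38 and Hist2h4 by -1.50 ± 0.44. Of 73 nuclear genes of oxidative phosphorylation, 19 fell, among them Cox4i1 (-1.01 ± 0.20) and Sdhb (-0.81 ± 0.18), and 4 rose (19 and 4 adjusted over the list alone; median -0.26). Those that rose, named after their values were seen, were Ndufa5 (0.80), Ndufs4 (0.53), Uqcrb (0.82) and Cox6c (0.81). These 3 lists were lower than other genes by camera with Benjamini-Hochberg adjustment: ribosomal proteins adjusted p = 2.11e-06, histones 0.000730 and oxidative phosphorylation 0.00704, each with adjusted p = 0.751 with an estimated correlation. In cytosolic control library 1 the histone median lay -1.59 from the other controls (shERa -1.35), the ribosomal protein median -0.35 (-0.53) and the oxidative phosphorylation median 0.02 (-0.26). Rpl5 lost its call without any 1 of shCtrl replicates 2, 3 and 4 and shERa replicates 2, 3 and 4. Hist2h4 lost its call without shCtrl replicate 4. Ndufa5 and Uqcrb lost their calls without either of shCtrl replicates 2 and 3. Ndufs4 and Cox6c lost their calls without any 1 of shCtrl replicates 2, 3 and 4 and shERa replicates 1, 2, 3 and 4. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p then reached 0.169 for Rpl5, 0.0771 for Hist2h4, 0.0656 for Ndufa5, 0.264 for Ndufs4, 0.0647 for Uqcrb and 0.205 for Cox6c.

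Of 13 mitochondrially encoded mRNAs, 7 rose and 0 fell (8 and 0 adjusted over the list alone; median 0.85), with mt-Nd5, a subunit of complex I, going from 917 ± 342 to 1954 ± 282 CPM and mt-Cytb changing by 0.90 ± 0.25. Of 24 mitosis genes, 10 rose and 0 fell (10 and 0 adjusted over the list alone; median 0.28). Mki67, a proliferation marker, went from 12.9 ± 7.11 to 92.1 ± 30.2 CPM (2.81 ± 0.37), and the centromere and spindle genes Cenpe, Cenpf and Kif11 changed by 2.19 ± 0.32, 1.99 ± 0.29 and 1.60 ± 0.30. Of 22 double strand break repair genes, 8 rose and 0 fell (8 and 0 adjusted over the list alone; median 0.70), including the checkpoint kinase gene Atr (1.59 ± 0.44), the helicase gene Blm (1.52 ± 0.45), Rad50 (1.52 ± 0.36) and Nbn (1.48 ± 0.30). By camera with Benjamini-Hochberg adjustment these 3 lists were higher than other genes, with adjusted p = 0.00704 for the mitochondrial mRNAs, 0.0407 for mitosis and 0.0384 for repair, and adjusted p = 0.751 with an estimated correlation for each. The mitosis list lost camera's call without shCtrl replicate 1 (adjusted p = 0.295), without shERa replicate 2 (adjusted p = 0.0534), without shERa replicate 3 (adjusted p = 0.0982), without shERa replicate 4 (adjusted p = 0.0694) and without cytosolic control library 1 alone (adjusted p = 0.331). The repair list lost camera's call without shCtrl replicate 1 (adjusted p = 0.184), without shERa replicate 3 (adjusted p = 0.0683), without shERa replicate 4 (adjusted p = 0.0654) and without cytosolic control library 1 alone (adjusted p = 0.177). In cytosolic control library 1 the medians of these lists lay 0.92, -0.41 and -0.20 from the other controls, in that order, against 1.02, 0.13 and 0.72 for shERa. mt-Cytb lost its call without shCtrl replicate 2. Blm lost its call without shERa replicate 3. In these fits the highest adjusted p by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was 0.0565 for mt-Cytb and 0.0640 for Blm.

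The comparison of polysome-associated RNA asked which mRNAs bound by more than 3 ribosomes differ between shERa and shCtrl cells. Col1a2 went from 498 ± 85.3 to 8.38 ± 3.26 CPM, and Postn, Col6a3, Pdgfrb and Col3a1 changed by -5.67 ± 0.58, -5.46 ± 0.64, -4.94 ± 0.38 and -4.20 ± 0.49. Cd200 went from 18.8 to 0.202 CPM, the latter from 3 reads in all. Also among the 10 largest falls were Npffr1 (-5.69 ± 0.56), Asb4, a ubiquitin ligase adaptor gene (-4.71 ± 0.53), Chst11, a chondroitin sulfotransferase gene (-4.69 ± 0.62), and Pcsk9, which encodes a regulator of the LDL receptor (-4.58 ± 0.61). Cdx2 rose from 0.364 ± 0.311 to 19.3 ± 2.89 CPM, and Krt19, an epithelial keratin gene (chromosome 11, 100140810 to 100145926), from 79.8 ± 28.7 to 592 ± 472 CPM. Wnt4, Nov, Cdc42ep5, Hsd17b14, Gsta1, Ptprf, Tspan15 and Fam102a completed the 10 largest rises, with log2 changes from 2.34 for Fam102a to 3.27 for Wnt4. Here too, the naming rule took only called genes of at least 5 CPM in which 4 of 4 shERa libraries lay beyond every shCtrl library. That lack of overlap was thus set by the rule.

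On polysomes, 624 of 10880 genes differed, 255 higher and 369 lower, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (two-sided, adjusted p under 0.05). In 1047 genes (9.62%) the 4 shERa and 4 shCtrl libraries did not overlap, where chance gives 2.86%. Without shCtrl replicate 1 the majority turned, with 557 of 1077 genes higher and 520 lower. The count was 354 without shCtrl replicate 2 and 351 without shCtrl replicate 3. It was 411 without shERa replicate 2, 323 without shERa replicate 3 and 398 without shERa replicate 4. With the 3 replicates per hairpin also on arrays it was 341, with the 8 polysome libraries fitted alone 373, and with a covariate for the leading axis within groups 986.

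Of 29 TGF-beta and extracellular matrix genes, 15 fell and 2 rose on polysomes (18 and 2 adjusted over the list alone; median -0.96), and the list was lower than other genes (camera, adjusted p = 2.32e-10, and adjusted p = 0.107 with an estimated correlation). Id1 (0.90 ± 0.16) and Id3 (0.95 ± 0.17), named after their values were seen, rose; both encode inhibitors of basic helix-loop-helix factors. Of 12 mesenchymal genes, 2 fell and 0 rose (5 and 1 adjusted over the list alone; median -0.55), and those that fell were Zeb1, a repressor of epithelial genes (-1.10 ± 0.27), and Mmp2, a matrix protease gene named after its values were seen, from 3.20 to 0.297 CPM. That list was lower than other genes (camera, adjusted p = 0.0412, and adjusted p = 0.268 with an estimated correlation). The mesenchymal list lost camera's call without shCtrl replicate 1 (adjusted p = 0.0783), without shERa replicate 3 (adjusted p = 0.0528) and without shERa replicate 4 (adjusted p = 0.0817). Krt18, the other keratin past the threshold among the 5 tested of 19 epithelial genes, rose by 1.20 ± 0.27. The epithelial list did not pass camera on polysomes (adjusted p = 0.112) or in cytosolic RNA (adjusted p = 0.603). Camera passed it on polysomes without shCtrl replicate 3 (adjusted p = 0.0458) and without shERa replicate 2 (adjusted p = 0.0191). Zeb1 lost its call without any 1 of shCtrl replicate 2 and shERa replicates 2, 3 and 4. Mmp2 lost its call without any 1 of shCtrl replicates 1 and 4 and shERa replicates 1, 3 and 4. Krt18 lost its call without shERa replicate 4. Without those replicates, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave adjusted p up to 0.0708 for Zeb1, 0.110 for Mmp2 and 0.0556 for Krt18.

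Of 20 chaperones of the unfolded protein response, which fold proteins in the endoplasmic reticulum, 7 fell and 0 rose (10 and 0 adjusted over the list alone; median -0.57). Sec24d, a coat protein gene of vesicles leaving that organelle, changed by -1.13 ± 0.22, Pdia4 by -0.92 ± 0.27, Hspa5 by -0.91 ± 0.25 and Hsp90b1 by -0.90 ± 0.26. Of 23 cytosolic aminoacyl tRNA synthetase genes, 3 fell and 0 rose (3 and 0 adjusted over the list alone; median -0.49), namely Tars (-1.24 ± 0.24), Lars (-0.95 ± 0.26) and Kars (-0.69 ± 0.21). Of 25 cholesterol genes, 1 fell and 0 rose (2 and 0 adjusted over the list alone; median -0.27), namely Pcsk9. By camera with Benjamini-Hochberg adjustment the chaperones (adjusted p = 0.000337, and adjusted p = 0.268 with an estimated correlation), synthetases (0.000934 and 0.759) and cholesterol genes (0.0173 and 0.767) were lower than other genes. The cholesterol list lost camera's call without shERa replicate 2 (adjusted p = 0.231). Pdia4, Hspa5 and Hsp90b1 lost their calls without any 1 of shCtrl replicates 2 and 3 and shERa replicates 2, 3 and 4. Lars lost its call without any 1 of shCtrl replicates 2 and 3 and shERa replicates 2 and 3. Kars lost its call without any 1 of shCtrl replicates 2 and 3 and shERa replicates 1, 2, 3 and 4. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p then reached 0.171 for Pdia4, 0.171 for Hspa5, 0.169 for Hsp90b1, 0.162 for Lars and 0.190 for Kars.

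Of 79 ribosomal protein mRNAs, 0 rose and 0 fell on polysomes by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (0 and 0 adjusted over the list alone), with a median log2 change of 0.33 and with Rpl8 at 0.14 ± 0.21. At an unadjusted p under 0.05, 17 rose and 0 fell, and DESeq2 called 6 higher and 0 lower and limma voom 0 and 0. Of 73 oxidative phosphorylation genes, 2 fell, Ndufs1 (-1.09 ± 0.31) and Sdha (-0.84 ± 0.25), and 0 rose (0 and 0 adjusted over the list alone), while the median was 0.20. By camera with Benjamini-Hochberg adjustment, both lists as a whole were higher than other genes, with adjusted p = 1.09e-06 and 0.000842, and adjusted p = 0.759 with an estimated correlation for each. The oxidative phosphorylation list lost camera's call without shCtrl replicate 4 (adjusted p = 0.0519). Ndufs1 lost its call without any 1 of shCtrl replicates 2 and 3 and shERa replicates 2 and 3. Sdha lost its call without any 1 of shCtrl replicates 2 and 3 and shERa replicates 2, 3 and 4. In these fits the highest adjusted p by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was 0.140 for Ndufs1 and 0.210 for Sdha.

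The test of the difference between the polysome and the cytosolic change asked which mRNAs respond differently in the 2 kinds of RNA. Of the 10 highest differences, 6 were of histone genes: Hist1h4d went from 191 ± 93.8 to 58.4 ± 16.4 CPM in cytosolic RNA and from 734 ± 204 to 977 ± 462 CPM on polysomes, a difference of 2.12 ± 0.49, and Hist2h4, Hist1h2ap, Hist1h1e, Hist1h2ab and Hist2h2ac differed by 2.05 ± 0.60, 1.98 ± 0.57, 1.95 ± 0.52, 1.94 ± 0.56 and 1.92 ± 0.65. Slc34a2, a phosphate transporter gene, went from 40.1 ± 10.96 to 6.75 ± 2.35 CPM in cytosolic RNA and from 124 ± 37.7 to 139 ± 53.9 CPM on polysomes (2.73 ± 0.40). Cdx2 (2.47 ± 0.79), Pskh1, a kinase gene (1.84 ± 0.44), and Rnd2, a Rho family gene (1.72 ± 0.42), completed the 10 highest. Most histone mRNAs lack the poly(A) tail that Smart-seq2 relies on, so the histone differences may not follow the main form. Mki67 went from 12.9 ± 7.11 to 92.1 ± 30.2 CPM in cytosolic RNA and from 20.9 ± 8.60 to 18.4 ± 8.14 CPM on polysomes (-2.97 ± 0.53). The 10 lowest were Zfp52, Kif20b, Dmxl1, Bcl2, Haus3, Kif18a, Prpf39, Mki67, Gcc2 and Rpgrip1l, from -3.41 for Zfp52 to -2.91 for Rpgrip1l. Bcl2 encodes an inhibitor of apoptosis, Kif18a a mitotic kinesin, Gcc2 a Golgi protein, Rpgrip1l a ciliary protein and Prpf39 a splicing factor.

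The difference passed in 1769 of 10880 genes, 563 with a higher and 1206 with a lower polysome than cytosolic change, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (two-sided, adjusted p under 0.05). DESeq2's size factors moved the median of all genes by 0.15 and the share with a higher polysome change from 31.8% to 51.0%, and library size alone moved them by -0.18 and to 12.4%. The count was 3337 without shCtrl replicate 1, 659 without shCtrl replicate 2, 659 without shCtrl replicate 3 and 569 without shCtrl replicate 4. It was 887 without shERa replicate 2, 444 without shERa replicate 3, 918 without shERa replicate 4 and 3282 without cytosolic control library 1 alone. The split by direction moved as well: the polysome change was the higher one in 1334 of the 3337 genes without shCtrl replicate 1, in 68 of the 569 without shCtrl replicate 4, in 49.1% of the 2065 without shERa replicate 1 and in 45 of the 444 without shERa replicate 3. With the 3 replicates per hairpin also measured on arrays, 159 genes passed, 4 higher and 155 lower. Analysis of partial variance, which regresses polysome on cytosolic values, called 4 genes, 0 higher and 4 lower, and reversed 7 of the named genes: Rnd2, Kif20b, Haus3, Mki67, Zfp62, Kif11 and Rad50. Cdx2 lost its call without any 1 of shCtrl replicate 4 and shERa replicates 2, 3 and 4. Hist2h4 lost its call without any 1 of shCtrl replicates 2, 3 and 4 and shERa replicates 3 and 4. Hist1h2ap and Hist1h1e lost their calls without any 1 of shCtrl replicates 2 and 4 and shERa replicate 3. Hist1h2ab lost its call without any 1 of shCtrl replicates 2 and 4 and shERa replicates 2, 3 and 4. Hist2h2ac lost its call without any 1 of shCtrl replicates 2, 3 and 4 and shERa replicates 2, 3 and 4. Rnd2 lost its call without shERa replicate 3. Without those replicates, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave adjusted p up to 0.171 for Cdx2, 0.107 for Hist2h4, 0.121 for Hist1h2ap, 0.0748 for Hist1h1e, 0.0942 for Hist1h2ab, 0.136 for Hist2h2ac and 0.0666 for Rnd2.

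Of 79 ribosomal protein mRNAs, 31 were above and 0 below (45 and 0 adjusted over the list alone; median 0.74) their cytosolic change on polysomes, with Rps14, Rpl36 and Rps10 at 1.41 ± 0.31, 1.32 ± 0.33 and 1.30 ± 0.31. Of 18 histone mRNAs, 9 were above and 0 below (12 and 0 adjusted over the list alone; median 1.69). Of 73 oxidative phosphorylation mRNAs, 15 were above and 2 below (20 and 2 adjusted over the list alone; median 0.42), with Atp5g2, an ATP synthase gene, at 1.13 ± 0.24, and with the complex I gene Ndufs1 (-1.50 ± 0.43) and the complex II gene Sdha (-1.16 ± 0.35) as those below. Of 24 mitosis mRNAs, 0 were above and 10 below (0 and 10 adjusted over the list alone; median -0.50), including Kif11 (-2.36 ± 0.44), Cenpf (-2.21 ± 0.42) and the checkpoint kinase gene Bub1 (-2.11 ± 0.51). Of 22 double strand break repair mRNAs, 0 were above and 6 below (0 and 8 adjusted over the list alone; median -0.86), including Blm (-2.37 ± 0.67), Rad50 (-2.19 ± 0.54) and Nbn (-2.10 ± 0.44). By camera with Benjamini-Hochberg adjustment the first 3 lists were higher than other genes, with adjusted p = 2.07e-13, 7.24e-05 and 5.62e-06, and the last 2 lower, with 0.00941 and 0.0458. All 5 had adjusted p = 0.981 with an estimated correlation. The mitosis list lost camera's call without cytosolic control library 1 alone (adjusted p = 0.242). The repair list lost camera's call without shCtrl replicate 1 (adjusted p = 0.0621), without shCtrl replicate 3 (adjusted p = 0.117), without shERa replicate 3 (adjusted p = 0.0823), without shERa replicate 4 (adjusted p = 0.0727) and without cytosolic control library 1 alone (adjusted p = 0.269). Rpl36 lost its call without either of shCtrl replicate 4 and shERa replicate 3. Ndufs1 lost its call without any 1 of shCtrl replicates 2 and 3 and shERa replicates 2 and 3. Sdha lost its call without any 1 of shCtrl replicates 2 and 3 and shERa replicates 2, 3 and 4. Bub1 lost its call without either of shCtrl replicate 2 and shERa replicate 3. Blm lost its call without any 1 of shCtrl replicates 3 and 4 and shERa replicates 2 and 3. Rad50 lost its call without either of shCtrl replicate 3 and shERa replicate 3. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p then reached 0.0651 for Rpl36, 0.103 for Ndufs1, 0.0920 for Sdha, 0.0635 for Bub1, 0.0990 for Blm and 0.0525 for Rad50.

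Of 17 genes for modification of the wobble uridine of tRNAs, which serves the decoding of codons ending in A or G, 1 rose in cytosolic RNA, the methyltransferase gene Alkbh8 (2.07 ± 0.39), and 2 fell, the thiolation gene Ctu2 (-1.05 ± 0.21) and Trmt112, a methyltransferase partner (-0.52 ± 0.19); adjusted over the list alone, 1 rose and 1 fell. On polysomes 0 passed (0 adjusted over the list alone), with the Elongator gene Elp3 at -0.78 ± 0.24 and adjusted p = 0.0535 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. At an unadjusted p under 0.05, 0 rose and 2 fell there, and DESeq2 called 1 lower and limma voom 0. Elp3 was near the threshold: it passed without shCtrl replicate 4 or shERa replicate 1 (adjusted p = 0.0476 and 0.0452), with library size alone (0.0363), thinned to equal depth (0.02605) and with a covariate for the leading axis within groups (0.0325), by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and by DESeq2 (0.029). The difference between changes passed for Ctu2 (0.92 ± 0.30) and Alkbh8 (-2.59 ± 0.57). Camera gave adjusted p = 0.115, 0.813 and 0.427 in cytosolic RNA, on polysomes and for the difference, while fry gave adjusted p = 0.0388 (down), 0.642 and 0.355. The list's median in cytosolic control library 1 lay -0.33 from the other controls, against -0.40 for shERa. In cytosolic RNA, Trmt112 lost its call without any 1 of shCtrl replicates 2, 3 and 4 and shERa replicates 3 and 4. In these fits the highest adjusted p by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was 0.124 for Trmt112. For the difference between changes, Ctu2 lost its call without any 1 of shCtrl replicates 2 and 4 and shERa replicates 2, 3 and 4. Without those replicates, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave adjusted p up to 0.127 for Ctu2.

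Called genes were sorted into 3 modes. Abundance genes changed in both kinds of RNA in 1 direction with no difference between the changes called, as Col1a2, Pdgfrb and Postn did, and numbered 288, of which 100 were higher and 188 lower. The abundance genes that were higher had medians of 1.41 in cytosolic RNA and 1.70 on polysomes, and those lower -1.57 and -1.60. Offset genes, whose cytosolic change was larger than their polysome change with the difference called, numbered 1358, and Mki67, Kif20b and Hist1h4d were among them. The 986 offset genes that were higher in cytosolic RNA had medians of 1.37 there and -0.30 on polysomes, and the 372 that were lower had -0.74 and 0.26. Translation genes, changed on polysomes with no cytosolic change called, numbered 117, of which 49 were higher and 68 lower. Bcl2 (-3.19 ± 0.72), the kinase gene Nek1 (-2.76 ± 0.62), the semaphorin gene Sema3a (-2.57 ± 0.46), which went from 23.5 ± 4.52 to 4.84 ± 1.17 CPM on polysomes, and Galnt7 (-2.23 ± 0.42) were in this mode by the difference between changes. These differences include cytosolic changes that were not called: Bcl2 had 1.74 to 6.68 CPM in cytosolic shCtrl and 6.08 to 11.1 CPM in cytosolic shERa libraries. On shERa polysomes Bcl2 had only 0.538 to 2.97 CPM, and its polysome call was lost without several single replicates, as given below.

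Zfp62 (-2.90 ± 0.61) and the chromatin remodeller gene Atrx (-2.87 ± 0.45) were among the offset genes with the largest differences. In simulated libraries in which the called cytosolic changes carried over to polysomes in full, 2285 abundance genes and 0 offset genes were called (mean of 5 runs). These libraries were drawn independently around group means, without a deviation such as that of cytosolic control library 1. They cannot show how many offset genes such a deviation would give. In the measured libraries, offset genes numbered 2568 without shCtrl replicate 1, 526, 530 and 445 without shCtrl replicates 2, 3 and 4, and 733, 383 and 720 without shERa replicates 2, 3 and 4. Abundance genes numbered 187 without shERa replicate 3. Translation genes numbered 298, 26, 31 and 58 without shCtrl replicates 1 to 4 and 262, 45, 17 and 54 without shERa replicates 1 to 4. Without cytosolic control library 1 alone, offset genes numbered 2659, 1356 of them among the 1358, and translation genes 198, 97 of them among the 117. The replicates also on arrays gave 139 offset and 11 translation genes, and translation genes numbered 249 by DESeq2 and 67 by limma voom. Modes were not sorted by analysis of partial variance, which called 4 differences in all.

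Over the 3580 genes past the cytosolic threshold, the slope of the polysome on the cytosolic log2 change was 0.28 ± 0.17 (jackknife SE over 8 replicates), 0.10 ± 0.10 for the 2115 higher genes and 0.65 ± 0.24 for the 1465 lower genes. Simulated libraries, drawn without a shared library state, gave 0.91 with full carry-over. With no effect simulated, a mean of 0.2 genes per run passed the cytosolic threshold over 5 runs. The slope of 0.07 there is therefore no usable baseline. Genes past the polysome threshold gave a slope of 1.08. Genes picked in some replicates and measured in the others gave a mean slope of 0.59, which describes no single pick. Picks with replicate 1 gave 0.78 to 0.85 over 76 to 152 genes, and the others gave 0.35 to 0.37 over 3185 to 4488 genes. Over the replicates left out in turn the slope ran from 0.18, without shCtrl replicate 1, to 0.39, without shCtrl replicate 4. It was 0.18 without cytosolic control library 1 alone, 0.18 over genes with at least 50 reads on average, 0.35 with a covariate for the leading axis within groups and 0.36 corrected for gene span. Both thresholds were passed upward by 105 genes (49.6 if independent) and downward by 193 (49.7 if independent), and 21 passed in opposite directions.

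**Figure D3:**
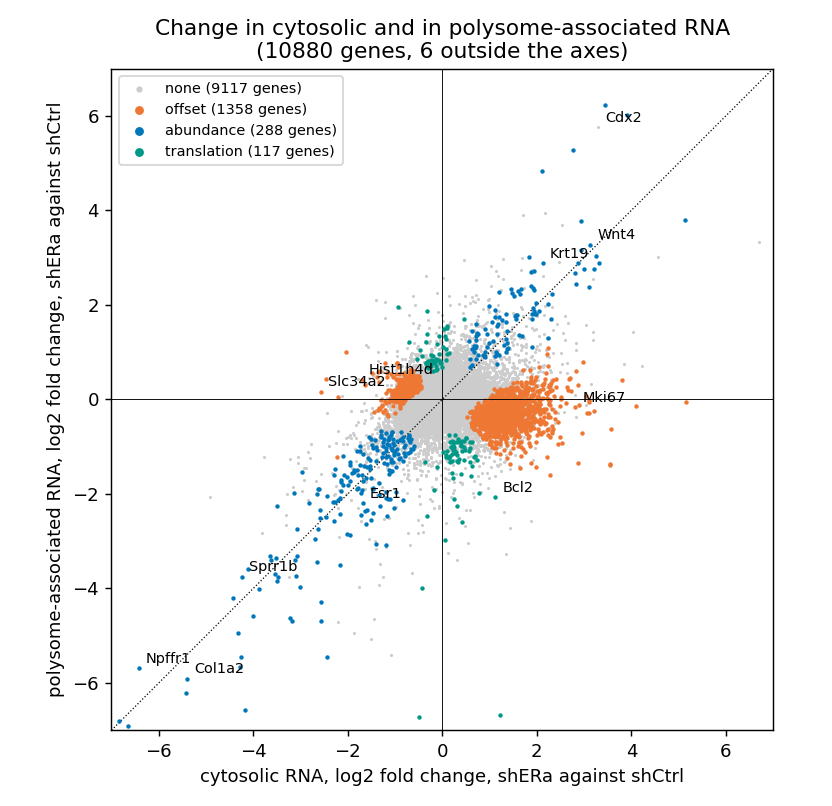
Polysome against cytosolic log2 change of shERa against shCtrl; each point is 1 tested gene, coloured by mode, the solid lines mark 0 and the dotted line marks equal change. The 986 offset genes higher in cytosolic RNA have a median polysome change of -0.30.

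**Figure D4:**
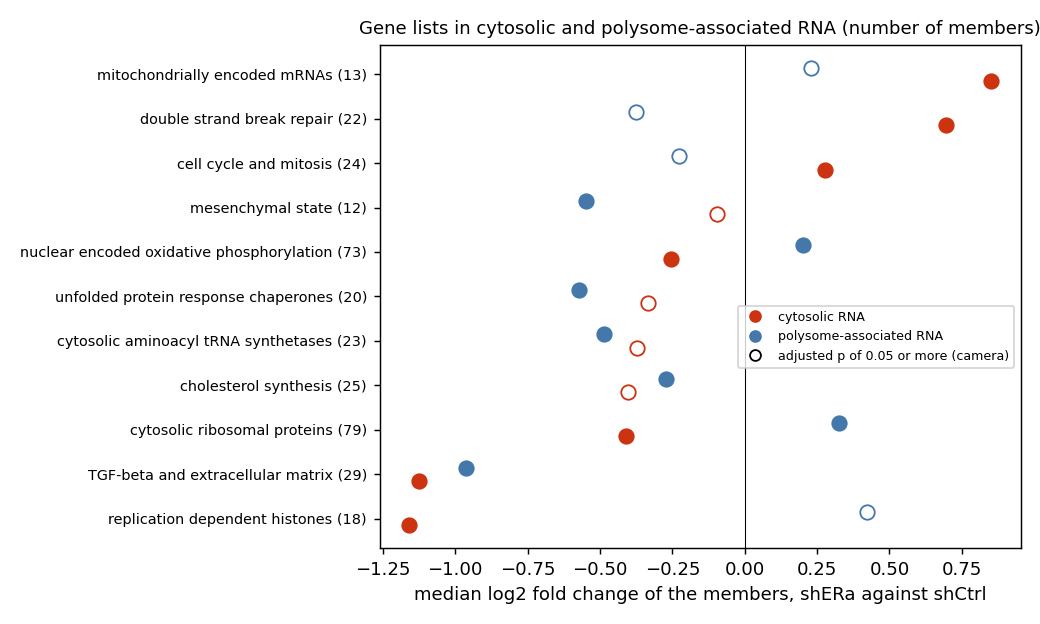
Median log2 change of shERa against shCtrl in cytosolic (red) and polysome-associated (blue) RNA for each gene list called in these comparisons or in the difference between them; filled points passed camera with its preset correlation of 0.01 and open points did not. The histone median was -1.16 in cytosolic RNA and 0.42 on polysomes.

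The comparison of polysome-associated with cytosolic RNA in shCtrl cells asked which mRNAs were over- or under-represented on polysomes. Mitochondrially encoded mRNAs, which are translated inside the organelle, were among the lowest: mt-Nd1, the lowest named, went from 8911 CPM in cytosolic RNA to 299.6 CPM on polysomes (-4.89 ± 0.21), and mt-Co2, mt-Atp8, mt-Nd2, mt-Nd4 and mt-Co1 differed by -4.05 ± 0.36, -3.71 ± 0.53, -3.64 ± 0.23, -3.52 ± 0.25 and -3.28 ± 0.27. The ferritin genes Fth1, at 17810 CPM in cytosolic RNA, and Ftl1 differed by -4.15 ± 0.25 and -2.85 ± 0.22. Among the highest were Hist2h2ac (2.80 ± 0.46), Hist1h2ae (2.21 ± 0.38), Gtpbp10, a GTPase gene (2.21 ± 0.37), Hist1h1b (2.09 ± 0.49), Hist1h2ab (2.04 ± 0.40) and Hist1h4d (1.95 ± 0.35). Lars2 (2.29 ± 0.42), which encodes a mitochondrial synthetase and holds a stretch similar to ribosomal RNA, went from 1261 to 6144 CPM. Smart-seq2 copies poly(A) RNA, and most histone mRNAs lack such a tail, so their values may not follow binding of ribosomes to the main form. Polysome replicate 3 held the highest histone share of its group, 0.255% in shCtrl and 0.416% in shERa. It also held the highest Lars2 share, 0.905% and 0.961%. The cause was not tested. Atf4 (-1.26 ± 0.23) and Ddit3 (-1.30 ± 0.26), stress factors with upstream reading frames, were lower on polysomes.

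Of 13 mitochondrially encoded mRNAs, 13 were lower and 0 higher (13 and 0 adjusted over the list alone; median -3.28), and of 18 histone mRNAs, 0 were lower and 12 higher (0 and 15 adjusted over the list alone; median 1.74). Of 79 ribosomal protein mRNAs, 21 were lower and 0 higher (27 and 1 adjusted over the list alone; median -0.31), with Rps12 at -2.03 ± 0.24 and Rplp0 at -1.76 ± 0.19. Of 25 other mRNAs with a 5' terminal oligopyrimidine tract (TOP), 7 were lower and 1 higher (11 and 3 adjusted over the list alone; median -0.35), with the poly(A) binding protein gene Pabpc1 at -2.37 ± 0.24 and the elongation factor gene Eef1a1 at -1.15 ± 0.20, and Nap1l1, named after its values were seen, higher by 0.73 ± 0.23. By camera with Benjamini-Hochberg adjustment, adjusted p = 1.86e-26 for mitochondrial, 1.83e-10 for histone, 1.10e-06 for ribosomal protein and 0.0307 for other TOP mRNAs. With an estimated correlation the mitochondrial list kept its call (adjusted p = 0.0190 with an estimated correlation), and the others had 0.394, 0.949 and 0.949. The other TOP list lost camera's call without shCtrl replicate 1 (adjusted p = 0.207), without shCtrl replicate 4 (adjusted p = 0.0812), without shERa replicate 1 (adjusted p = 0.0589) and without shERa replicate 3 (adjusted p = 0.0503). In shCtrl cells 1207 of 10880 genes differed between the 2 kinds of RNA, 556 higher and 651 lower on polysomes, and in shERa cells 5525 did, 2218 higher and 3307 lower, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The median over all tested genes was -0.30 in shERa and -0.03 in shCtrl cells, so the shERa split by direction depends on scaling. The shERa count is not given over the alternatives here. The share of the shCtrl genes that were higher, 46.1%, depended on scaling and filter: it was 53.9% with DESeq2's size factors, 55.2% by DESeq2, 55.4% corrected for gene span and 58.9% over genes with at least 50 reads on average. It was also 52.9% without shCtrl replicate 1, 58.5% without shCtrl replicate 2, 58.3% without shERa replicate 1 and 53.3% without cytosolic control library 1 alone. The shCtrl count was 612, 337 and 669 without shCtrl replicates 2, 3 and 4, 459 with the replicates also on arrays and 1922 with a covariate for the leading axis within groups. Hist1h1b lost its call without either of shCtrl replicates 2 and 3. Nap1l1 lost its call without any 1 of shCtrl replicates 2, 3 and 4. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p then reached 0.0867 for Hist1h1b and 0.172 for Nap1l1.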

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

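The counts over other splits of the samples were planned; every test of an explanation was chosen after its result was seen.

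In 21 of 428 groups of 4 values, the highest or lowest sample lay far from the other 3, with a gap to its nearest neighbour above 0.829 of the group's range, where chance gives about 5% of groups, or 21.4. Cytosolic control library 1 was that sample in 9 groups. It had 12981 genes detected against 12368 in the nearest control (gap 0.877 of the range). In the same library stood Cd200 at 33.99 CPM against 20.8 in the nearest control (gap 0.881), Greb1 at 28.1 CPM against 11.02 in the nearest control (gap 0.878), Tap1 at 26.4 CPM against 45.04 in the nearest control (gap 0.921), mt-Nd5 at 1427 CPM against 770.2 in the nearest control (gap 0.905), Cox4i1 at 1692 CPM against 2349 in the nearest control (gap 0.933), mt-Atp8 at 23.4 CPM against 9.86 in the nearest control (gap 0.887), mt-Co1 at 4010 CPM against 2726 in the nearest control (gap 0.830) and Areg at 46.6 CPM against 23.8 in the nearest control (gap 0.956). Cytosolic shCtrl replicate 2 lay apart for Bst2 at 24.6 CPM against 35.01 (gap 0.982) and Xbp1 at 317 CPM against 372 (gap 0.837). Cytosolic shERa replicate 1 lay apart for Bst2 at 29.97 CPM against 18.2 (gap 0.8294). Cytosolic shERa replicate 2 lay apart for Zfp445 at 3.28 CPM against 11.8 (gap 0.846). Polysome shCtrl replicate 2 lay apart for Wnt4 at 0.261 CPM against 5.31 (gap 0.870). Polysome shCtrl replicate 3 lay apart for Tspan15 at 12.2 CPM against 3.42 (gap 0.862) and Atrx at 22.4 CPM against 14.9 (gap 0.877). Polysome shCtrl replicate 4 lay apart for Tars at 129 CPM against 224 (gap 0.912). Polysome shERa replicate 1 lay apart for Col1a2 at 3.50 CPM against 9.91 (gap 0.970). Polysome shERa replicate 2 lay apart for Cenpf at 12.5 CPM against 6.99 (gap 0.857). Polysome shERa replicate 3 lay apart for Cdx2 at 15 CPM against 20.5 (gap 0.924) and Galnt7 at 7.14 CPM against 4.76 (gap 0.928).

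Fold changes of polysome-associated over cytosolic RNA differed between shCtrl and shERa cells in 1769 genes, by the test of the difference between the changes. Each count was set against the 35 splits of the 8 replicates or libraries into 4 and 4. Only 1 split, the real one, gave a count as high, and 1 of 35 is the smallest share possible. No correction was made over the counts. Mixed splits put the hairpin difference into the spread within groups, which lowers their counts. They therefore cannot exclude chance for the size of a count. The real counts and the highest of the other splits were 3580 and 148 genes in cytosolic RNA, 624 and 88 on polysomes, and 1769 and 275 for the difference between these changes. They were 288 and 1 for abundance genes, 1358 and 0 for offset genes and 117 and 50 for translation genes. For polysome-associated against cytosolic RNA in shCtrl, where the splits take the 8 libraries as exchangeable, they were 1207 and 102 over 35 splits. Over the 8 splits that swap fractions within a replicate number, counted after the result was seen, they were 1207 and 0, and 8 splits are too few for a share under 0.05.

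The 1358 offset genes, among them Mki67 and Kif20b, differed in cytosolic RNA with little change on polysomes. After a correction for gene span, 725 of the 1358 were still called, among 1048 offset genes in that fit. Bias by gene span, as corrected here, does not account for those 725 calls and may account for others. Coding length and GC share were not tested. A swapped label of cytosolic control library 1 is excluded. Abundance genes lay there at a median of 0.0678 of the way from the other controls to shERa, and offset genes at 0.576. Mixing of shERa RNA into that library is thus not the whole cause of the offset position. A minor admixture is not excluded: abundance genes higher in shERa lay at 0.219, against 0.546 for offset genes that were higher. A state of libraries or cultures not tied to the hairpin may account for part of the pattern: across 9456 genes, control library 1 minus 2 correlated with shERa minus controls 3 and 4 at r = 0.688, where control 2 minus 3 against shERa minus control 4 gave -0.0242, and genes are not independent replicates. An effect of the knockdown stays open. The count rose to 2659 without control library 1, but that library lies toward shERa. Leaving it out widens the group difference under either explanation, so the rise cannot decide between them. With a covariate for the leading axis within groups, taken from these same libraries, 959 offset genes were called, 812 of them among the 1358.

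Of 18 histone mRNAs, 11, Hist1h4d among them, fell in cytosolic shERa RNA and 7 did not pass, with a list median of -1.16. With an estimated correlation the list did not pass camera (adjusted p = 0.751). The list did not fall on polysomes: its median there was 0.42 (quartiles 0.15 and 0.55), with 16 of 18 members above 0. These reads may not follow the main form of histone mRNA, so fewer cells in S phase are not excluded. A state of libraries or cultures not tied to the hairpin may account for the cytosolic fall. Histone genes took 0.0527% of reads in cytosolic control library 1, against 0.0846 ± 0.0104% in the other controls and 0.0428 ± 0.00762% in shERa. Smart-seq2 copies RNA with poly(A) tails, which most histone mRNAs lack, so these reads are a minor form or primed otherwise, and no value separates these. An effect of the knockdown stays open.

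Of 29 TGF-beta and extracellular matrix genes, 15, Col1a2 among them, fell, 2 rose and 12 did not pass in cytosolic RNA. The counts were the same on polysomes, but the genes were not all the same. Skil rose in cytosolic RNA only, Id3 on polysomes only and Id1 in both. With an estimated correlation the list did not pass camera (adjusted p = 0.560 and 0.107). The values argue against loss of fibroblasts that express Dcn, Lum, Dpt and Pi16. These genes, abundant in fibroblasts, together reached 0.109% of Col1a2 in cytosolic control RNA. Lum, Thy1 and Fap had 0 reads in all 16 libraries (up to 0.0324 CPM each). Of that marker list, Pdgfra at 20.4 CPM in cytosolic shCtrl RNA and Col3a1 at 44.1 CPM were measured in these cells. Loss of cells that lack the other markers was not tested. An off-target effect of the hairpin or drift of the stable line cannot be told apart from loss of the receptor, since the design holds 1 hairpin against the target. Knockdown of ERα is a possible explanation, untested beyond this hairpin.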

How the results depend on the processing

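4 alternatives were chosen after seeing the data: leaving out cytosolic control library 1 alone, thinning to equal depth, a covariate for the leading axis of deviations within groups, and a correction for gene span; the others were planned. Over the named genes and all alternatives, 3403 values kept direction and side of the threshold, 407 lost the call, 13 gained it and 7 reversed; for lists these were 1530, 60, 33 and 1. Except where fewer samples or another threshold account for a shift, the cause was not tested. With the 3 replicates per hairpin also on arrays, counts were 2018 (cytosolic), 341 (polysome), 159 (difference), 459 (polysome against cytosolic RNA), 139 (offset) and 11 (translation). At a threshold of 0.15 they were 1421 (polysome), 3549 (difference), 2507 (polysome against cytosolic RNA), 535 (abundance), 2566 (offset) and 405 (translation). The 8 polysome libraries fitted alone gave 373. With the covariate the polysome count was 986, polysome against cytosolic RNA 1922, and 12 cytosolic lists passed, with DNA replication and G1/S now higher (adjusted p = 0.0105). Cytosolic and polysome RNA were isolated in parallel, but the labels do not state that equal numbers share a lysate. Deviations of cytosolic and polysome libraries with the same number correlated at 0.314, 0.181, 0.117 and 0.0514 in shCtrl and 0.332, 0.189, 0.0439 and 0.226 in shERa. For shCtrl replicate 2 and shERa replicate 3 the own number did not correlate best, so pairing by number stays unsettled. Across hairpins, cytosolic shERa and polysome shCtrl libraries correlated at 0.415 for replicate 1 and at -0.0750, -0.0514 and 0.0501 for replicates 2 to 4. With a replicate block the counts were 3966, 769, 2184 and 1531 for the 4 contrasts. The lists passing camera went from 7, 7, 5 and 4 to 6, 9, 5 and 3 in that order. With the culture as a replicate block the counts were 2692 (difference) and 2121 (polysome against cytosolic RNA). With the replicate block by number, Elp3 passed on polysomes (adjusted p = 0.0399) and Pten in cytosolic RNA (adjusted p = 0.02235), by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Translation genes numbered 249 by DESeq2 and 67 by limma voom.

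Analysis of partial variance, which regresses polysome on cytosolic values, called 4 genes for the difference and reversed Rnd2 (-0.24), Kif20b (0.14), Haus3 (0.70), Mki67 (0.64), Zfp62 (0.000700), Kif11 (0.0265) and Rad50 (0.86); the cause was not tested. The slope was 0.59 with genes picked in part of the replicates, where the 3 picks with replicate 1 gave 0.78 to 0.85 and the others 0.35 to 0.37, and 1.08 over genes past the polysome threshold. With an estimated correlation 0 lists passed in cytosolic RNA, 0 on polysomes, 0 for the difference and 1 for polysome against cytosolic RNA; fry passed 9, 3, 0 and 5 in that order, and in cytosolic RNA it did not pass the mitosis and oxidative phosphorylation lists. Without cytosolic control library 1 alone the difference count was 3282, offset genes 2659 and translation genes 198. Over the replicates left out in turn, counts ran from 2420 to 4981 (cytosolic), 323 to 1077 (polysome), 444 to 3337 (difference), 337 to 1744 (polysome against cytosolic RNA), 187 to 368 (abundance), 383 to 2568 (offset) and 17 to 298 (translation), and 3 (without that library alone) to 5 lists passed for the difference.

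DESeq2 moved the median of all genes by -0.12 in cytosolic RNA (46.6% of called genes higher) and 0.15 for the difference (52.2%), and the span correction by -0.14 (46.3%) and 0.20 (49.9%). No called list's median changed sign under these, DESeq2's size factors in edgeR, library size alone, the covariate or leaving out that library. Thinned to 2769566 reads per library, counts were 3271, 581, 1682 and 1178 for the 4 contrasts, but the polysome libraries held only 2769566 to 5774729 reads before thinning, which leaves open how depth limits the polysome and difference counts. In the self-test 15 of 50 genes at 2-fold were called on polysomes and 0 of 50 for the difference. Codon and UTR features, with GC share and coding length as covariates or a threshold of 0.15 as alternatives, were not run.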

Other observations

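The list tests here were planned; the group of Zfp genes and its counts were chosen after the result was seen.

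Of 32 estrogen response genes, 7 rose and 5 fell in cytosolic shERa RNA (7 and 5 adjusted over the list alone), and 5 rose and 2 fell on polysomes (5 and 2 adjusted over the list alone). Greb1, an estrogen receptor target, fell in both, with log2 changes of -3.08 ± 0.49 in cytosolic RNA and -2.73 ± 0.52 on polysomes. Krt19, another member, rose in both, by 2.12 ± 0.43 and 2.89 ± 0.45. The other members that fell in cytosolic RNA, named after their values were seen, were Xbp1 (-0.78), Car12 (-1.13), Adcy1 (-1.32) and Amfr (-0.53), and those that rose were Mybl1 (2.25), Ugcg (1.54), Areg (1.35), Nrip1 (1.22), Tgfa (1.02) and Sgk1 (0.60). On polysomes Bcl2 fell too (-2.07), and Igfbp4, Areg, Rara and Wfs1 rose by 0.76, 0.99, 0.69 and 0.97, also named after their values were seen. The list did not pass camera in cytosolic RNA (adjusted p = 0.876, where its median was 0.01 and the test's direction down) or on polysomes (adjusted p = 0.263). In cytosolic RNA, Adcy1 lost its call without any 1 of shCtrl replicates 2 and 4 and shERa replicates 3 and 4. In cytosolic RNA, Amfr lost its call without any 1 of shCtrl replicate 2 and shERa replicates 3 and 4. In cytosolic RNA, Tgfa lost its call without any 1 of shCtrl replicates 2, 3 and 4 and shERa replicates 1, 2, 3 and 4. In cytosolic RNA, Sgk1 lost its call without any 1 of shCtrl replicates 1, 2, 3 and 4 and shERa replicates 2, 3 and 4. In these fits the highest adjusted p by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was 0.218 for Adcy1, 0.119 for Amfr, 0.203 for Tgfa and 0.259 for Sgk1. Without cytosolic control library 1 alone, Sgk1 lost its cytosolic call too (adjusted p = 0.0661, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). On polysomes, Bcl2 lost its call without any 1 of shCtrl replicates 2 and 3 and shERa replicates 1, 3 and 4. On polysomes, Igfbp4 lost its call without either of shCtrl replicate 2 and shERa replicate 4. On polysomes, Areg and Rara lost their calls without any 1 of shCtrl replicates 2 and 3 and shERa replicates 2, 3 and 4. On polysomes, Wfs1 lost its call without any 1 of shCtrl replicates 3 and 4 and shERa replicates 1 and 4. Without those replicates, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave adjusted p up to 0.110 for Bcl2, 0.0562 for Igfbp4, 0.0952 for Areg, 0.195 for Rara and 0.119 for Wfs1.

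Of 29 interferon response genes, 3 rose and 4 fell in cytosolic RNA (2 and 3 adjusted over the list alone), and 0 rose and 5 fell on polysomes (0 and 5 adjusted over the list alone). Psmb8, Psmb9 and Tap1, genes of antigen processing, fell in cytosolic RNA, with log2 changes of -2.45 ± 0.30, -3.14 ± 0.41 and -1.87 ± 0.25, and on polysomes, with -2.48 ± 0.31, -1.99 ± 0.43 and -1.50 ± 0.26. In cytosolic RNA Bst2 also fell (-0.68), and Rsad2, Ifit2 and Gbp3 rose by 2.10, 1.83 and 1.51. Parp9 (-1.29) and Trim30a (-1.79) completed those that fell on polysomes; Bst2, Ifit2, Gbp3, Parp9 and Trim30a were named after their values were seen. Camera gave adjusted p = 0.659 in cytosolic RNA, with a median of 0.21 and a direction of down, and 0.0591 on polysomes, where camera's adjusted p passed without shCtrl replicate 2 (0.0439), without shCtrl replicate 3 (0.0458), without shCtrl replicate 4 (0.0145) and without shERa replicate 1 (0.000226). The list's median in cytosolic control library 1 lay 0.78 from the other controls, against 0.41 for shERa. In cytosolic RNA, Bst2 lost its call without any 1 of shCtrl replicates 3 and 4 and shERa replicates 2, 3 and 4. In cytosolic RNA, Rsad2 lost its call without shCtrl replicate 2. In cytosolic RNA, Gbp3 lost its call without any 1 of shCtrl replicates 2, 3 and 4 and shERa replicates 1, 3 and 4. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p then reached 0.124 for Bst2, 0.0586 for Rsad2 and 0.163 for Gbp3. On polysomes, Parp9 lost its call without any 1 of shCtrl replicates 2 and 3 and shERa replicates 1, 2 and 4. On polysomes, Trim30a lost its call without any 1 of shCtrl replicates 1 and 3 and shERa replicates 2 and 3. In these fits the highest adjusted p by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was 0.136 for Parp9 and 0.138 for Trim30a. In cytosolic RNA, Bst2 also lost its call without cytosolic control library 1 alone (adjusted p = 0.0517, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).

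Genes with Zfp symbols, chosen as a group after their values were seen, included 268 tested members, of which 88 rose (32.8%, against 19.4% of all tested genes) and 11 fell in cytosolic shERa RNA. On polysomes 0 rose and 1 fell by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (18 and 12 at an unadjusted p under 0.05, 5 and 2 by DESeq2, 0 and 1 by limma voom), and 46 of the 268 were offset genes. Their median in cytosolic control library 1 lay 0.35 above the other controls, against 0.64 for shERa. Of the markers of other cell types, Cd74 had 1.24 CPM in cytosolic shCtrl and 0.0259 CPM in cytosolic shERa RNA, Lyz2 had 2.72 and 1.32 CPM, and Ptprc, C1qa and Cdh5 had 0 reads in all 16 libraries, which allows up to 0.0324 CPM each.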
